A study of Drosophila melanogaster with 2 samples.

How the data were processed

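RNA of ovaries was measured in 2 libraries, 1 from flies heterozygous and 1 from flies homozygous for the CG5508 mutation, kept at 25 °C, per the labels. The genotypes were taken from the strain labels, which write the gene as GC5508 where the titles have CG5508, and were read as the same gene. Per the labels' protocols, the libraries were made from total RNA with not-so-random priming, in which primer sequences that match ribosomal RNA are left out of the random primer pool. The submitters' processing notes name TopHat 1.4.1, Bowtie 0.12.8, bedtools and DESeq 1.8.2 and the genome build dm3, without saying what each was used for.

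The authors deposited 5 lists. A pair held features higher and lower with uniquely mapped reads, another pair those with up to 10 mappings per read, and the last held strands of piRNA clusters higher with uniquely mapped reads. The 8 strands of 6 clusters in the last list were also in the list of all higher features, with identical values. Per the file headers, the deposited signal values are normalized read counts, as a mean over both libraries and per library. The fold column is a ratio of heterozygous over homozygous values, per the file headers, and was inverted here for higher features. The log2 column is the log2 of that ratio as deposited by the authors. The p-value columns, raw and adjusted, are the authors' own, and the largest adjusted p was 0.0801 in the higher and 0.0933 in the lower list of uniquely mapped reads. For up to 10 mappings, the authors' largest adjusted p was 0.0985 in the higher and 0.0873 in the lower list. These p-values rest on 1 library per genotype and carry no replicate check, and no p-values were computed here.

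In the lists with up to 10 mappings, 4 per-library columns, headed zucMUT and zucCD in each list, had names that match neither sample's labels and were not used. The authors' mean, fold and p-value columns of those lists were used. The deposited log2 fold with uniquely mapped reads minus that with up to 10 mappings was the same, −0.00585, in 16 of 26 shared entries of the lower lists. The same difference held in 18 of 108 shared entries of the higher lists. On this basis the lists were taken to hold the same comparison, which no label states.

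Per-library values with uniquely mapped reads were whole multiples of 0.8647 normalized units in the homozygous and of 1.156 in the heterozygous library. All 151 values of each library were whole reads within a tolerance of 0.001 read. These steps correspond to size factors of 1.16 and 0.865 whose product is 1. Reads per feature were recovered by dividing by the step. The ratio of each feature was given an exact conditional binomial interval (Clopper-Pearson, 95%), which covers counting error only. Shares were given exact binomial intervals by the same method, also where the count was 0. A feature at 0 in 1 library was set against a floor of 3 counts in that library. The recovered reads of the lists were not given to a count model, since the lists hold selected features alone. The interval calculation was tested on simulated data of 20000 features with independent Poisson counts. Such an interval holds its level under that model by design, so the test checks the calculation alone. The simulated features were not selected by fold, as the listed ones were, so the shares below need not hold for listed features. For features simulated as homozygous over heterozygous with uniquely mapped reads, intervals held the true ratio in 95.7% of 16000 features at 1-fold. Among 1000 features each, the shares were 95.0% at 2-fold, 95.9% at 4-fold, 96.5% at 8-fold and 97.0% at 16-fold.

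A feature was counted once per gene, insertion or cluster strand, represented by the entry with the highest mean where isoforms were listed apart. The 113 and 30 deposited entries for uniquely mapped reads gave 57 and 23 features, and the 367 and 27 entries with up to 10 mappings gave 270 and 21. Positions came from the Ensembl release 115 annotation of build BDGP6 (dm6), matched by FlyBase identifier and never converted from dm3. Of the genes and insertions, 47 of 49 higher and 23 of 23 lower ones with uniquely mapped reads were matched, as were 244 of 256 and 21 of 21 with up to 10 mappings. A gene was taken to contain an insertion when the insertion overlapped its dm6 span on the same strand. The strands of a cluster were counted as separate features with different values, such as 538 and 193 homozygous reads for cluster 08 plus and minus. Whether the authors' counting of genes and insertions used strand is not given in the sources used here.

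The text names features by a rule. In each list, among features with at least 20 normalized reads, these were the 10 with the largest fold, the 5 with the highest level and up to 4 examples from each of 23 fixed lists. The level was that of the homozygous library for higher and of the heterozygous library for lower features, and the authors' mean with up to 10 mappings. The muscle and eggshell lists were given in full. Genes that contain an insertion, and the ribosomal RNA features, Hsromega and features grouped by position in the closing part, were chosen after their values were seen. The fixed lists covered follicle cell (soma) dominant, germline dominant and telomeric transposons, and LTR, non-LTR and DNA transposon classes. They also covered the piRNA pathway, glycerolipid synthesis, eggshell, yolk and its uptake, heat shock, immune response, DNA damage and apoptosis, and histones. The remaining lists held markers of germline, follicle cells, muscle, fat body, hemocytes, gut and testis, the mitochondrial genome and noncoding RNA genes. Members without an identifier in the annotation were not counted. Lists were written from general knowledge of the field, not from these libraries.

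The sample groups, the rule for names, the lists, the comparisons and most alternatives were fixed before the data were examined. The alternatives fixed in this way were an adjusted p under 0.01, a change of at least 4-fold and a mean of at least 50 normalized reads. Homozygous values were also divided or multiplied by 1.25 with a 2-fold minimum, pseudocounts of 1 and 10 were added, the other read treatment was used, and overlap was taken by family or gene name. Added after the data were seen were counts of every deposited entry, counts without genes that contain a listed same-strand insertion, counts and transposon shares with each family once, and the number of cluster strands with up to 10 mappings. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.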

Results

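Transcripts of *Drosophila melanogaster* ovaries were sequenced from flies heterozygous or homozygous for z3-5967, a mutation of CG5508, the gene minotaur (mino). The flies were 3 to 5 days old. There was 1 library per genotype, so no difference below has a replicate check. The deposited lists hold features, meaning genes, single transposon insertions and single strands of piRNA clusters, that passed the authors' test as higher or lower in the homozygous library. Levels of features outside the lists were not used here, so a feature that is not listed cannot be called unchanged. Total depth per library was not known, because the lists hold part of each library. In the lists of uniquely mapped reads, the listed features held 85648 reads of the homozygous library and 67961 reads of the heterozygous library. The authors' size factors put the homozygous library at 1.34 times the depth of the heterozygous one. Intervals in parentheses are exact 95% intervals on the reads. They cover counting error only and compare these 2 libraries, not the genotypes.

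The mutated gene was looked up first. Mino encodes a glycerol-3-phosphate acyltransferase, an enzyme of glycerolipid synthesis, and lies on chromosome arm 3R from 27925191 to 27933077 in the dm6 build (FBgn0027579). It was in none of the 5 lists, so the lists hold no level of mino with which to check the genotype labels.

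The first comparison asked which transcripts were more abundant in homozygous ovaries. The study's title places mino in the production of piRNAs, small RNAs that silence transposons. With uniquely mapped reads, transposon insertions of 11 families, 8 strands of 6 piRNA clusters and 29 genes rose. HeT-A, the retrotransposon that maintains fly chromosome ends, led the list with 9 insertions. These listed insertions rose 4.79-fold to 113.5-fold, with a median of 54.5-fold. HeT-A{}6268, on chromosome 4 from 1301834 to 1307750 in dm6, rose 113.5-fold from 53.2 to 6040 normalized reads (85.0 to 155). HeT-A{}6276 on the same chromosome had the highest homozygous level of the list, 6299 against 116 normalized reads, a 54.5-fold rise (44.7 to 67.0). HeT-A{}6253, HeT-A{}6274 and HeT-A{}4800 rose 107.7-fold, 71.6-fold and 56.1-fold.

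Retrotransposons of the gypsy group rose as well. Gypsy5{}1006, on 3L from 15295823 to 15298608 in dm6, held 136.6 normalized reads in homozygous ovaries and a single read in heterozygous ones, a 118-fold rise (20.9 to 4695). Gypsy5{}103 rose 9.89-fold (5.04 to 22.2). Stalker2{}106 rose 56.8-fold and HeT-Tag{}6279, beside a HeT-A insertion, 69.5-fold, each from 1 heterozygous read. Also among LTR retrotransposons, 1 McClintock insertion rose 20.9-fold (11.8 to 40.9) and 1 gypsy12 insertion 7.92-fold (5.77 to 11.1). A flea insertion, of a family in none of the fixed lists, rose 21.2-fold (7.01 to 105) from 3 heterozygous reads. Fw3 and Rt1b, which lack LTRs, rose 6.30-fold and 3.67-fold. The span of the Rt1b insertion, Rt1b{}1666, on 2R from 6256173 to 6322173 in dm6, also contains gypsy12{}2214 on the opposite strand. In the homozygous library gypsy12{}2214 held 445 reads and Rt1b{}1666 held 358, so not all reads of gypsy12{}2214 were counted for Rt1b{}1666. Other sequence in this span was not examined, so the reads of Rt1b{}1666 remain uncertain. The DNA transposons S and transib4 rose 9.76-fold and 7.44-fold. Insertions made up 20 of the 57 higher features, or 35.1% (exact interval 22.9 to 48.9). None of the 23 lower features was an insertion (exact interval 0 to 14.8%). Insertions with 1 heterozygous read have wide intervals, and HeT-Tag{}6279 and HeT-A{}6253 span few bases beside longer HeT-A insertions, so their reads are uncertain. Counted with up to 10 mappings per read, the authors' deposited table gave 71.3-fold for HeT-A{}6268, 54.0-fold for HeT-A{}6253, 33.0-fold for HeT-A{}6274, 60.3-fold for gypsy5{}1006 and 40.0-fold for gypsy5{}103.

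**Figure D1:**
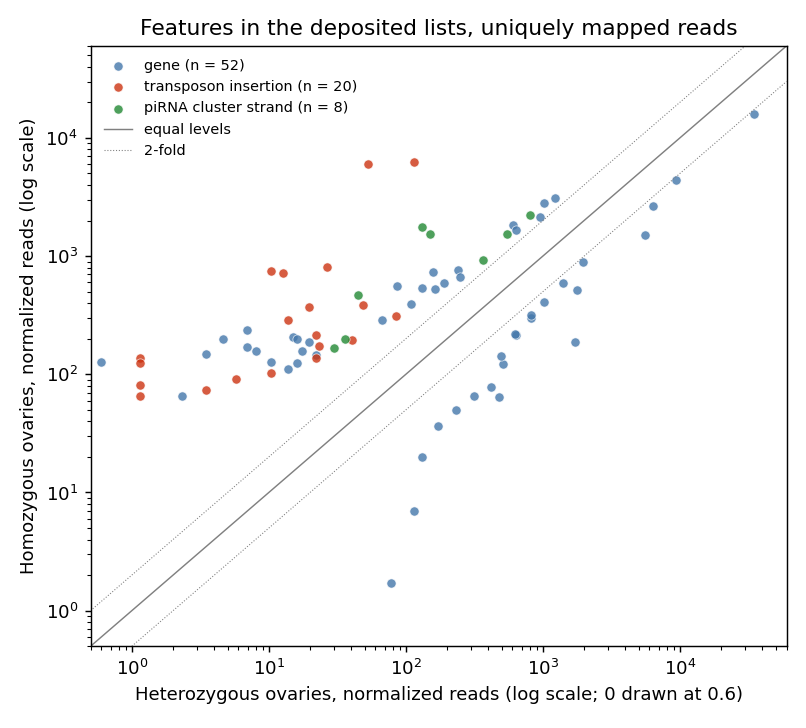
Normalized reads of each feature in the lists of uniquely mapped reads, heterozygous library on the horizontal and homozygous library on the vertical log axis, coloured by kind of feature, with lines at equal levels and at 2-fold. All 20 transposon insertions and all 8 piRNA cluster strands lie above the line of equal levels.

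The list of piRNA clusters, the loci that give rise to piRNA precursors, held 8 strands of 6 clusters. It holds higher strands by its definition, and 0 of the 23 lower features with uniquely mapped reads was a cluster strand. The minus strand of flam, the flamenco locus that targets gypsy-type elements in follicle cells, rose 13.5-fold (11.2 to 16.5), from 131 to 1763 normalized reads. The plus strand of flam was in none of the lists. Which strand of a cluster gives rise to its precursor was not examined here, so a rise of a strand is not read as a rise of precursors. Cluster 08 rose on its plus strand 10.3-fold (7.45 to 14.7) and on its minus strand 5.55-fold (3.67 to 8.71). The plus strand of cluster 14 rose 10.2-fold (8.52 to 12.3) and the minus strand of cluster 05 rose 5.55-fold (3.80 to 8.35). Rises were smaller at 42AB, a cluster read on both strands in the germline, with 2.81-fold on the minus (2.54 to 3.12) and 2.52-fold on the plus strand (2.22 to 2.86). The minus strand of cluster 11 held the most homozygous reads of these strands, 2211 normalized reads, and rose 2.73-fold (2.51 to 2.97). The clusters contain transposon sequence, so reads of other copies can be among those counted. Counted with up to 10 mappings per read, 14 strands of 9 clusters were listed, and the authors' deposited table gave 9.31-fold for flam, 5.22-fold for 08 plus and 2.85-fold for 08 minus. The largest cluster fold of the authors' deposited table, singled out after its value was seen, was 19.4 for the minus strand of cluster 02.

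**Figure D2:**
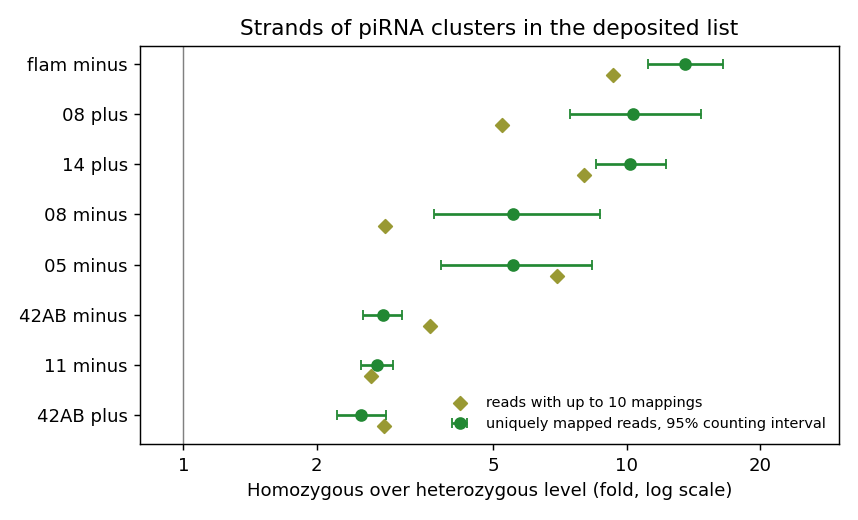
Fold of each listed piRNA cluster strand, homozygous over heterozygous library, on a log axis. Circles with bars are uniquely mapped reads with exact 95% counting intervals, and diamonds are the authors' values with up to 10 mappings per read. Among these 8 strands, flam minus has the highest fold under both read treatments.

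Among genes, spok, a cytochrome P450 of ecdysone synthesis on 3R from 3322810 to 3354486 in dm6, had 146 reads in the homozygous and 0 in the heterozygous library. Against a floor of 3 counts per library its ratio was 36.4, and the exact lower limit was 29.2-fold. GfA, named nAChRalpha7 in the dm6 annotation, rose 43.4-fold (16.7 to 161), from 4 heterozygous reads. The list with up to 10 mappings in the authors' deposited table gave 33.7-fold for spok and 19.4-fold for gfA. Of the fat body markers, 4 of 11 rose. These were the larval serum protein genes Lsp2 at 34.0-fold (15.4 to 93.5), Lsp1alpha at 12.3-fold and Lsp1beta at 9.07-fold, together with Fbp1, encoding a serum protein receptor, at 13.7-fold (7.85 to 26.1). Of the muscle markers, 5 of 22 rose, among them the actin gene Act87E at 3.23-fold, the myosin light chain gene Mlc2 at 3.19-fold and the titin-like gene sls at 3.03-fold. Msp-300 and bt rose 2.60-fold and 2.23-fold. Of the hemocyte markers, 1 of 11 rose, the collagen gene Cg25C at 2.68-fold (2.30 to 3.13). RpL28, a ribosomal protein gene, rose from 1220 to 3125 normalized reads, 2.56-fold (2.39 to 2.75). It contains snoRNA:Or-CD12 on the same strand, which rose 2.74-fold (2.55 to 2.96) to 2805 normalized reads. The snoRNA held 3244 homozygous and 884 heterozygous reads, against 3614 and 1055 for RpL28. If its reads were counted for both, they make up most of the RpL28 value, so a rise of RpL28 itself is uncertain.

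The lower features were all genes, and genes of the eggshell were among them. Of 25 eggshell genes, 5 fell and none was listed as higher. Cp19, a chorion protein gene on 3L from 8729865 to 8730604 in dm6, fell 9.08-fold (7.87 to 10.5), from 1705 to 188 normalized reads. Cp7Fa fell 5.41-fold (4.28 to 6.89), Cp38 3.67-fold (3.48 to 3.88) and Femcoat 3.47-fold (2.89 to 4.19). Cp15, the most abundant of them with 6339 heterozygous and 2670 homozygous normalized reads, fell 2.37-fold (2.27 to 2.48). In the same libraries the fat body, muscle and hemocyte markers named above were higher.

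The steepest falls outside this list were in low transcripts. CG43163 fell 44.8-fold (11.9 to 378), with 2 reads left in the homozygous library. The sodium channel subunit gene tipE fell 16.7-fold (8.17 to 39.8), from 100 to 8 reads. CG31661, CG12716, CG15570, CG10445 and CG31926 fell by 4.19-fold to 7.48-fold, and Cad74A, a cadherin gene, 4.63-fold (3.44 to 6.32). Of the abundant transcripts, the mucin-related gene Mur2B fell 2.11-fold (2.04 to 2.19). CR41602 and CR40596, typed as ribosomal RNA in the lists and annotated as ribosomal RNA pseudogenes in dm6, fell 2.18-fold and 2.19-fold. They share sequence with other copies, so their values are uncertain. Hsp26, a small heat shock protein gene, fell 2.82-fold (2.42 to 3.28). In the lower list with up to 10 mappings per read, the authors' deposited table gave 16.1-fold for CG43163 and did not hold Mur2B, CR41602 or CR40596. It added 1 gene, CG18675 at 6.52-fold, which overlaps tipE in dm6.

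**Figure D3:**
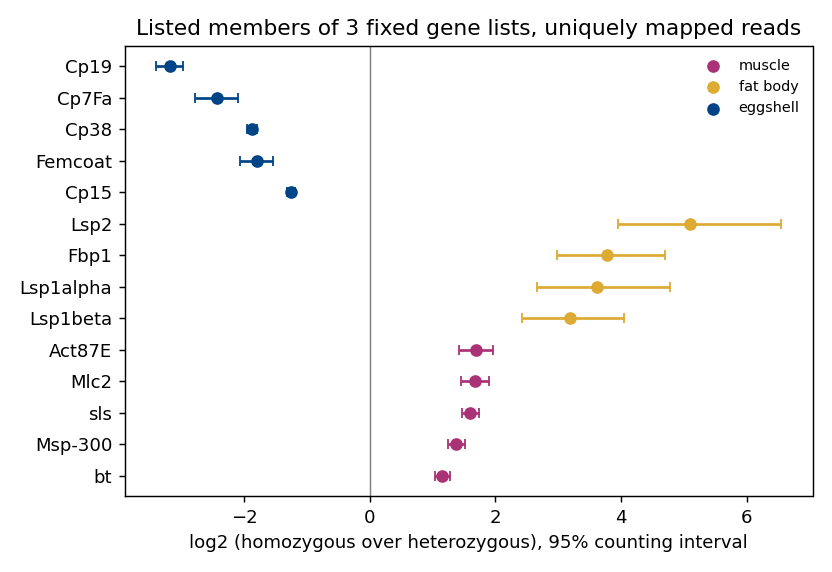
Log2 of the homozygous over the heterozygous level for the listed members of the eggshell, fat body and muscle lists, uniquely mapped reads, with exact 95% counting intervals. The 5 eggshell genes lie below 0, and the 4 fat body and 5 muscle genes above it.

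The same comparison with up to 10 mappings per read counted reads of repeated sequence that unique mapping leaves out. According to the authors' deposited table, 270 features rose, 184 of them insertions of 46 families, which is 68.1%. Copies of a family share reads, and with each family counted once the share was 34.8%, against 22.9% with uniquely mapped reads. Reads that may be shared between families were not removed from these shares. Lower features numbered 21, all genes, with 0 insertions (exact interval 0 to 16.1%). Per-library columns of these lists carry names outside this series and were not used, so the values are the authors' means and folds. By the median over insertions in the authors' deposited table, HeT-A rose 44.2-fold with 16 insertions, blood 109-fold with 10 and Transpac 67.7-fold with 5. Among the single insertions with the largest folds in the authors' deposited table were HeT-Tag{}6289 at 307-fold and blood{}1094 at 126-fold. Their means and folds in the authors' deposited table imply 2.32 normalized heterozygous reads each, as for 9 of the 10 blood insertions, so these folds rest on few reads and have no interval. HeT-Tag{}6288, HeT-Tag{}6291, HeT-Tag{}6292 and 3S18{}3956 were listed at 0 in the heterozygous library of the authors' deposited table, and no fold is given for them.

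Some families fixed as dominant in follicle cells and some fixed as dominant in the germline rose. Of 20 follicle cell families, 12 were higher. The medians, taken here over folds in the authors' deposited table, were 50.2-fold for gypsy5, 39.8-fold for Stalker2, 30.6-fold for mdg1 and 16.6-fold for gtwin. With uniquely mapped reads, 2 of the 20 families were higher, gypsy5 and Stalker2. Of 42 germline families, 20 were higher. Besides blood, Transpac and HeT-A, medians taken here over the authors' deposited folds were 28.4-fold for the finite values of 3S18, 26.4-fold for Burdock and 16.3-fold for the I element. With uniquely mapped reads, 2 of the 42 were higher, HeT-A and Rt1b. Rt1b was listed by 1 insertion, whose span also contains a gypsy12 insertion on the opposite strand. Of 5 telomeric elements 1 was listed, HeT-A. By class, 34 of 64 LTR families, 7 of 40 families without LTRs and 3 of 27 DNA transposon families were higher. The corresponding counts for uniquely mapped reads were 4, 3 and 2. The insertion with the highest mean was springer{}300, with 7459 normalized reads over both libraries and an 8.15-fold rise in the authors' deposited table. Insertions of 1 family share reads, so they are not independent measurements.

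**Figure D4:**
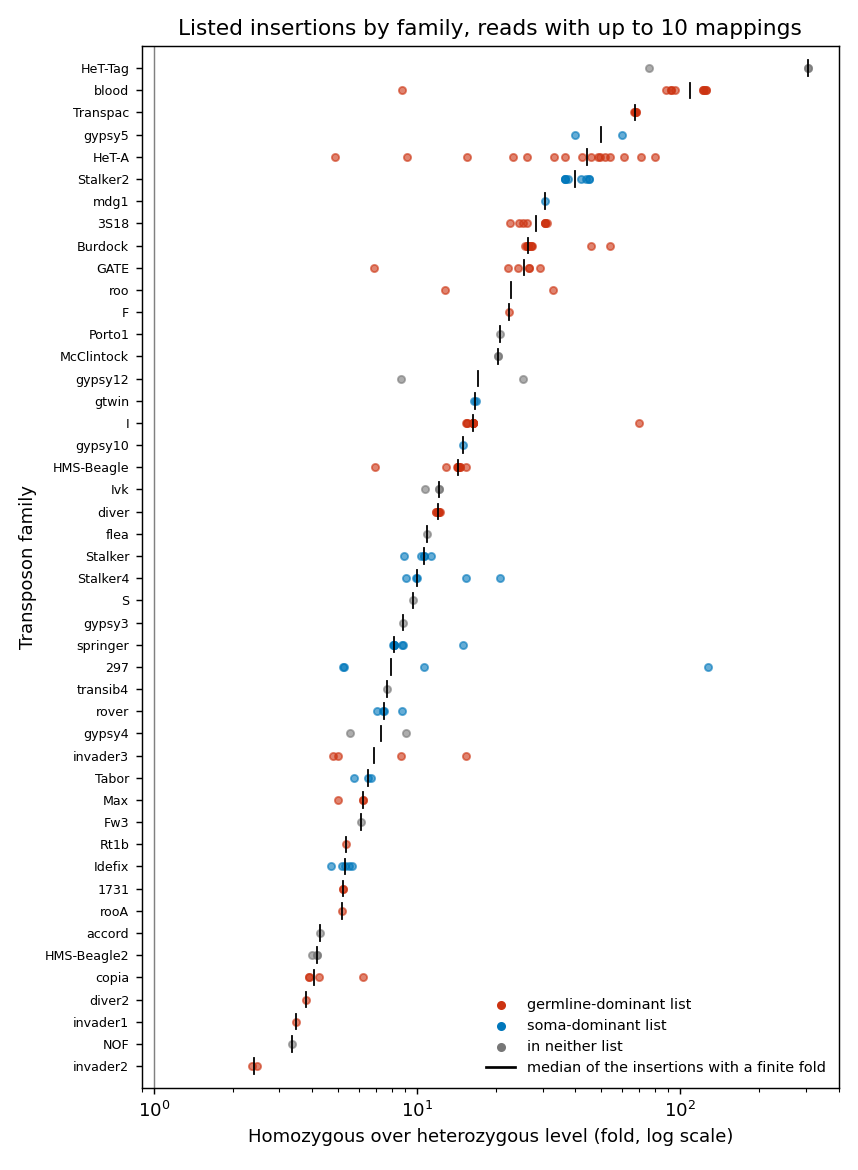
Fold of each listed insertion, homozygous over heterozygous library, on a log axis, by family, from the authors' values with up to 10 mappings per read. Colours mark the fixed germline and follicle cell (soma) lists, and black ticks are medians of finite folds. All plotted folds lie above 1 because the list holds higher features alone.

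Between the read treatments, 56 of the 57 higher features with unique mapping were also higher with up to 10 mappings. The exception was the muscle gene bt. Another 214 features were higher in the list with up to 10 mappings alone, made up of 164 insertions, 44 genes and 6 cluster strands. Those strands added 3 clusters, 02, 16 and 19. Of the 16 heat shock genes with an identifier, which did not include Hsromega, 6 were among the 44 genes. These were Hsp70 copies, at 4.05-fold to 4.49-fold in the authors' deposited table. The Hsp70 copies are near-identical and share reads, so their separate values are uncertain. Yeti had the highest mean of that list, 40548 normalized reads, and rose 2.84-fold in the authors' deposited table. Of the lower features, 20 were shared.

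The genes B4, kirre, CG34353 and CG7900 were among the 44. Each contains a Transpac insertion on its own strand, within an intron in dm6. In the authors' deposited table B4 rose 22.9-fold at a mean of 6491 normalized reads, while its insertion Transpac{}362 had a mean of 6075. For 16 of 23 genes with such an insertion, the gene's mean lay within 10% of the insertion's mean.

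**Figure D5:**
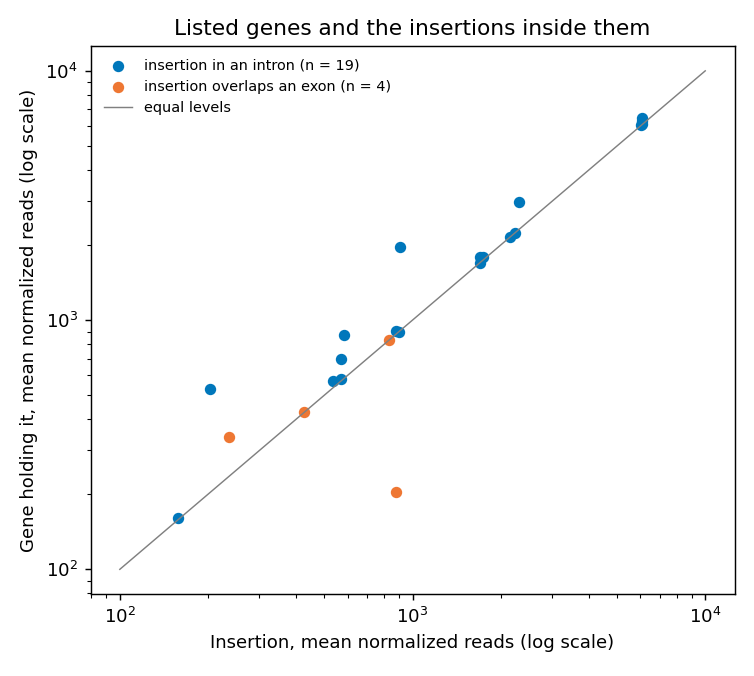
Mean normalized reads over both libraries of 23 listed genes, on the vertical log axis, against the listed same-strand insertion inside each, on the horizontal log axis. The 19 genes with an intronic insertion and the 4 with one overlapping an exon are coloured apart, and 16 points lie within 10% of the line of equal levels.

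Many groups had no member in any list. These were the 38 piRNA pathway genes, the 15 glycerolipid synthesis genes, the 4 genes for yolk proteins and their uptake and the 25 immune response genes. The same held for the 14 DNA damage and apoptosis genes, the 7 histone genes, the 20 germline and maternal markers and the 16 follicle cell markers. No member was listed of the 25 gut markers, the 22 testis markers, the 15 mitochondrial genes and the 5 noncoding RNA genes. Their levels were not analysed here.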

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

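Counts of every entry, of each family once and of cluster strands with up to 10 mappings were chosen after seeing the data. No paired analysis was possible because each genotype had 1 library, which also rules out leaving out a library. With an adjusted p under 0.01 in the authors' deposited table, features with uniquely mapped reads numbered 35 higher and 9 lower in place of 57 and 23, and cluster strands 5 in place of 8. Lower features with up to 10 mappings then numbered 10 in place of 21. A change of at least 4-fold left 10 lower features with uniquely mapped reads, 11 with up to 10 mappings and 5 cluster strands. These reductions follow from stricter thresholds on fixed lists. Counting every deposited entry gave 113 higher entries with uniquely mapped reads and a transposon share of 17.7%, since isoforms were then counted apart. With up to 10 mappings the transposon share was 68.1% in place of 35.1% and cluster strands numbered 14, and the cause was not tested. Counting insertions once per family left 132 higher features in place of 270, and a transposon share of 34.8% there and 22.9% with uniquely mapped reads. Other alternatives kept these counts within 1.5 times, and the overlap of 56 became 47 by name and 51 at a mean of at least 50. Of 79 finite folds in the lists of uniquely mapped reads, a pseudocount of 1 moved 0 and a pseudocount of 10 moved 14 outside their counting intervals, all lower. With up to 10 mappings, 13 of 75 moved, 9 of them lower. Depth limits features with few heterozygous reads, such as gypsy5{}1006, at 13.1-fold with a pseudocount of 10.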

Other observations

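Except for the remainder of genes after subtraction of their insertion, the tests of this part were chosen after the lists had been seen. The features grouped by position here were likewise chosen after their values were seen. The 9 HeT-A insertions higher with uniquely mapped reads lay in 2 places of dm6. On chromosome 4, 5 of them lay between 1278430 and 1320140 and rose 15.9-fold to 113.5-fold. On the X chromosome, 4 lay close together between 109756 and 122492 and rose 4.79-fold to 107.7-fold. The largest of these folds was that of HeT-A{}6253, from 116408 to 116442, and rested on 1 heterozygous read (19.0 to 4282). The next largest was 56.1-fold for HeT-A{}4800.

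Several lower genes were close neighbours in dm6. Cp15, at 3L 8728481 to 8729066, and Cp19, at 8729865 to 8730604, fell 2.37-fold and 9.08-fold. On the X chromosome, Cp7Fa from 8470888 and Cp38 from 8481837 fell 5.41-fold and 3.67-fold. CG32642, Mur11Da and CG12716, on X between 12959220 and 12976231, fell 2.71-fold, 2.58-fold and 6.63-fold. CG31926 and CG31661, on 2L between 1495460 and 1498583, fell 4.19-fold and 7.48-fold.

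Among features listed with up to 10 mappings alone, 5 features typed as ribosomal RNA, among them CR40581, rose 3.61-fold to 3.67-fold in the authors' deposited table, and they share reads. The heat-inducible noncoding RNA Hsromega, left out of the heat shock count above, rose 2.70-fold with up to 10 mappings in the authors' deposited table. The same table gave springer-like levels for blood{}2438, invader3{}1714 and gypsy3{}1250. Their means were 6796, 6661 and 6534 normalized reads, with 8.77-fold, 8.69-fold and 8.83-fold rises.

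Among genes higher with up to 10 mappings alone, 23 of 36 with a position in dm6, or 63.9% (46.2 to 79.2), contained a listed insertion on the same strand, against 0 of 26 (0 to 13.2) among genes higher under both read treatments. Same-strand insertions in listed genes numbered 24 and opposite-strand ones 1. Subtracting the insertion's normalized reads left a median remainder of 1.20-fold (quartiles 1.10 to 1.54) over the 10 of 23 genes with a remaining mean of at least 50. Among these, CG7900, neuroligin and scrib kept 2.19-fold, 1.92-fold and 1.62-fold. The genes had been chosen as not listed with uniquely mapped reads, and that choice by itself favours a small remainder. The remainder therefore cannot decide whether the genes' own transcripts changed. For bxd and CG42249, mean and fold equalled those of the insertion inside, 1701 normalized reads at 12.1-fold and 829 at 14.6-fold. CG9766, CG14669 and uif had remaining means of 0.863, 0.863 and 0.431 normalized reads. The listed rises of these genes thus rested almost wholly on reads also counted for the insertion. For the other genes, reads of the insertions may account for many of the listings, as a hypothesis. CG32850 had a mean of 205 against 878 for its insertion Stalker2{}1505, so not all of that insertion's reads were counted for it. Transcripts that start in an insertion and run into the gene stay open for the other genes. Insertions absent from these flies stay open for all.

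Of the fixed lists, 5 of 25 eggshell genes were lower, and 4 of 11 fat body and 5 of 22 muscle markers were higher. An equal loss of egg chambers that make eggshell would lower these genes by 1 factor. Yet the fall of Cp19 (7.87 to 10.5), the largest of the 5, was 3.83 times that of Cp15 (2.27 to 2.48), the smallest. In these 2 libraries the listed falls thus differed beyond counting error. The genes compared were the extremes of the listed falls, and 1 library per genotype shows no variation between libraries. The comparison therefore cannot decide on an equal loss, and an unequal loss was not tested and stays open. A smaller share of the main cell type would raise the listed fat body and muscle markers by 1 factor, yet their median log2 rises differed by 2.10, with SDs of 0.82 and 0.23, and the lowest fat body interval (Lsp1beta, 5.36 to 16.5) lay above the highest muscle one (Act87E, 2.69 to 3.90). These values concern the listed genes of 2 libraries, and low transcripts enter the lists with large folds, so they do not measure how far the groups differ between genotypes. Fat body tissue carried along in dissection could raise the 4 listed markers, but the levels of the other 7 were not analysed here, so it stays open beside an effect of the mutation.

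The mutation lies on chromosome 3, where homozygous flies may also be homozygous for linked variants. Of 21 lower protein-coding genes with uniquely mapped reads, 38.1% (18.1 to 61.6) lay on chromosome 3, and of 25 higher ones 44.0% (24.4 to 65.1). Of 13945 annotated protein-coding genes, 44.2% lay there. Both intervals include this share, so an effect of linked variants and one of the mutation cannot be told apart with this few genes.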
